A study of Mus musculus with 2 samples.

How the data were processed

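Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used, per the labels, to locate histone H3 acetylated on lysine 9 (H3K9ac) in whole heart of mice at postnatal day 0. H3K9ac is a histone mark found mainly at promoters and enhancers of transcribed genes. The labels give 1 group with 2 biological replicates: hearts of 15 newborn mice for replicate 1, and of an unstated number of newborn mice for replicate 2. Each replicate pooled males and females of the strain B6NTac;B6NCrl/Lap, and the libraries were size-selected to 300 to 500 bp. The labels name the same donor entry for both pools, so whether the pools came from separate litters is not known.

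The authors deposited 4 peak lists on the mouse build mm10 (GRCm38). Per the deposited file listing, each replicate's list was derived from that replicate's filtered alignments and a control alignment. The pooled list was derived from both replicates with both controls, and the replicated list from the other 3 lists. Peak caller, version, peak threshold and the rule of replication are not given in the sources used here. The smallest deposited −log10 p was close to 2 in each list. Each peak carries a deposited signal value, which is the authors' own enrichment value and whose exact scaling is not given in the sources used here. The plan fixed beforehand called it the authors' fold; because its scale is not stated, it is called a signal value throughout. Each peak also carries the authors' −log10 of a peak p-value and, per the file format, a summit position. Signal values were used to describe, rank or filter peaks within a list. Between the replicates' lists they were set side by side and compared by rank correlation over shared peaks, without a test of their levels. The peak lists carry no read totals, so sequencing depth is unknown. A missing peak may mean absence of the mark or too few reads, and confidence intervals on shares (95%, exact Clopper-Pearson) cover the counting of peaks or genes, not biological variation.

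Gene models were those of GENCODE vM21 on GRCm38, and sequence was taken from the RefSeq copy of the same build. All peak ends lay within the chromosome lengths of that build. A protein-coding gene was called marked when a replicated region touched the 1 kb on either side of any of its annotated transcription start sites (TSSs). Regions were placed by their midpoint as promoter (within 1 kb of a TSS), exon, intron or intergenic, in that order. For motif and neighbourhood tests, a region that touched a TSS window was a TSS region, and a region over 2.5 kb from any annotated TSS was distal. Width at a gene was that of the widest region touching a TSS window after joining regions across gaps of up to 1 kb. A marked gene was called wide when this width lay in the top 10% of marked genes. Regions on unplaced contigs entered no gene or placement result.

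Peaks of 1 replicate were called shared when at least 50% of their own length was covered by peaks of the other. Gene lists were fixed before the data were examined, 29 in all, for heart muscle, metabolism, proliferation, other heart cell types, blood and other tissues. Of their 591 entries, 587 matched an annotated protein-coding symbol and 1 matched through a synonym. The other 3 (H19, Meg3 and Kcnq1ot1) are noncoding genes and were left out of the tests. Lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Odds ratios of all lists have 0.5 added to each cell, whether or not a cell is empty, which draws those of short lists nearly all marked towards 1; the p-values use the counts as they are. Ratios of summits to flanks likewise have 0.5 added to both counts. Odds ratios of CpG classes, X-linked, Hox and RefSeq start comparisons have nothing added. Numbers of distal regions by nearest protein-coding gene were compared with 100000 random lists matched on 10 classes of the size of the interval around each gene (permutation test, two-sided). Nearest gene is a convention and assigns no target. Members marked in 1 replicate and not in the other, at a −log10 p of at least 5, were compared by exact McNemar tests. Genes are not replicates, so each of these tests describes these peak lists and not a population of hearts. TSSs were classed by the CpG content of 500 bp windows around the most 5′ annotated start: high above 0.75 observed to expected with over 55% GC, low under 0.48, and intermediate otherwise. High was compared with low by Fisher's exact test, planned as two-sided; because that p was too small for the number format, the −log10 p of the upper tail is given. TSS sequence was called unique when at least 90% of the 32-base words taken every 50 bp in the 1 kb on either side of the most 5′ start occurred once in the genome. The interval on the X chromosome's signal difference came from 10000 bootstrap draws of genes and its p from 10000 permutations of chromosome labels. Consensus sequences of 16 motifs, fixed beforehand, were searched on both strands in the 400 bp around each region's summit and in a window of the same size 2 kb upstream, and compared by exact McNemar tests.

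Genes were named by a rule fixed beforehand. It takes 30 fixed genes, the 10 genes with the highest signal value and the 10 with the widest region. It also takes up to 5 unmarked members of each heart muscle list, and up to 5 marked members with the highest signal value of each blood or other-tissue list. The 5 distal regions with the highest signal value, the 5 genes with most distal regions and, per replicate, the 5 strongest genes marked in that replicate alone complete it. Genes outside this rule are named as chosen after their values were seen.

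The list and distal tests were tested on simulated data with all 21938 protein-coding genes. For the comparison of lists at the TSS with lists of 25 genes, 99% of runs at a marked rate of 0.95 against 0.6 gave p under 0.05. At a rate of 0.8 it was 53%, at 0.3 it was 85%, and with no difference 5%. For the distal comparison, 88% of runs with 3 times the regions and 4% with no difference passed, without adjustment. There the matching classes were random and the added regions were spread at random over all members. Real counts were more uneven between genes, so this power may be too high for them. For the motif comparison, with 2000 simulated regions, 100% of runs with the consensus planted in 5% of summits and 0% with none passed. It had fewer runs than the list and distal comparisons, so both shares are coarse estimates. Simulated summits and flanks had the same base composition, unlike the real windows, so these shares do not cover a difference in GC. The planted 5% also exceeded the 1.76% of real distal summits with the MEF2 consensus.

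Alternatives fixed beforehand were a stricter −log10 p of at least 10, a signal value of at least 4, the pooled list, each replicate's own list in turn, other TSS windows (500 bp and 2 kb), other overlap rules, other joining gaps and motif windows, and a background of genes whose TSS has high or intermediate CpG content. Some alternatives were added after the data were seen: genes with no neighbouring protein-coding TSS within 2 kb, genes with a low-CpG TSS, and a ranking by signal value in place of width. The low-CpG background was first run with genes marked at any TSS and then again with genes marked at that TSS, and both are reported. Shuffled consensus sequences holding the letters CG were left out before drawing. The shuffled sequences were first drawn 200 times and then, after those results were seen, 1000 times. The verdict was then read from a 95% interval on the share in place of the share itself. The bound set beforehand, 5%, stayed, and the verdicts are the same with the share itself in either run. No paired analysis applies, since there is 1 group. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.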

Results

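H3K9ac was mapped by ChIP-seq in whole hearts of newborn mice, with 2 biological replicates of 1 group. The authors' lists held 49087 peaks in replicate 1, 47609 in replicate 2 and 60370 when both were pooled. The replicated list, on which the results rest unless stated otherwise, held 26634 regions covering 29.3 Mb, with a median width of 850 bp. With no second group, the data answer which genes carried the mark in newborn heart and how far both replicates agreed. All 26634 replicated regions are identical to peaks of the pooled list, so their signal values are those of the pooled call. No SD can be taken from the replicated list. Values of both replicates come from their own lists and stand side by side to show how far they differed. They need not lie around the pooled value, as at Actc1 with 18.7 against 11.1 and 11.7. Depth is unknown.

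Genes of the cardiac muscle programme carried H3K9ac at their TSS almost without exception. Of 26 cardiac transcription factors, 25 were marked, among them Nkx2-5, Gata4, Tbx5, Tbx20, Hand2 and Mef2c, which specify the heart fields and drive cardiomyocyte genes. The sarcomere list had 29 of 30 members marked. Calcium handling and ion channels had 21 of 22 marked, including Ryr2, the calcium release channel, and Atp2a2, the calcium pump of the sarcoplasmic reticulum. The gap junction and intercalated disc list had all 12 marked. Across all 21938 protein-coding genes the share was 59.9% (95% interval 59.2 to 60.5). All 4 lists stood above other genes by Fisher's exact test, with adjusted p of 1.4e-04 for transcription factors, 2.1e-05 for sarcomere, 5.6e-04 for calcium and channels, and 0.00395 for the intercalated disc. The odds ratios, with 0.5 added to each cell as for all lists, were 11.4, 13.2, 9.62 and 16.8.

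At the heart genes given here with values of both replicates, the signal values differed by up to about 2 times. Elsewhere the gap could be larger, as at Krt10 of the epidermal list with 8.89 and 4.13. Some genes had a TSS peak in 1 replicate only. Tbx20, a T-box factor of the heart, had 22.2 and 11.3 in replicates 1 and 2, and Gata6 29.0 and 14.7. Hand2, a transcription factor of right ventricular development, had a replicated peak on chromosome 8 (57316369 to 57329679) that spans the whole gene, with a signal value of 40.8, and peaks of 39.8 and 29.6 in replicates 1 and 2. Nkx2-5 had a signal value of 25.3, with 20.7 and 18.1 in the replicates. Atp2a2 had 36.7, with 26.6 and 33.6. Ryr2 had 24.2, with 15.5 and 26.9, a gap in the other direction. Myh6, the alpha heavy chain of cardiac myosin, had 25.5, with 23.8 and 28.1. Actc1, the cardiac actin, had 18.7, with 11.1 and 11.7, and Tnnt2, cardiac troponin T, had 17.3, with 16.9 and 14.9. Tnni1, the troponin I form of the fetal heart, had 9.59 beside 17.9 for Tnni3, the adult form. Of the 30 genes fixed by name, all 24 that were marked had a TSS peak in both replicates' own lists. The other 6 (Csf1r, Hba-a1, Myod1, Alb, Neurod1 and Pou5f1) were touched by no peak of any of the 4 lists.

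Genes with chamber or conduction functions gave a mixed picture. Myl7, the atrial myosin light chain, had a signal value of 4.45 (3.83 and 4.81 in the replicates), against 17.9 (19.4 and 17.2) for Myl2, its ventricular counterpart. Nppa, which encodes atrial natriuretic peptide, had 4.18 and its neighbour Nppb, which encodes the B-type peptide, had 11.5. Atrial genes named after their values were seen ranged widely. Myl4, an atrial myosin light chain, had 19.6 (28.2 and 18.6), and the transcription factors Nr2f2 and Nr2f1 had 14.9 and 11.2. Stard10 had 10.6, Kcnj3 6.64 and Kcna5 5.91, and Bmp10 was unmarked. Sln, an atrial regulator of the calcium pump, was the unmarked member of the calcium list. Isl1, a factor of the second heart field and sinus node, and Xirp2, an actin-binding protein, were the unmarked transcription factor and sarcomere gene. The conduction system list had 10 of 14 marked and did not differ from other genes (odds ratio 1.56, adjusted p 0.444 by Fisher's exact test). Hcn4, the pacemaker channel, was marked with a signal value of 6.16, while Hcn1, Cntn2, Smoc2 and Isl1 were not. Smoc2 was touched by a pooled peak alone. Cardiac peptides and stress genes had 8 of 10 marked (odds ratio 2.28, adjusted p 0.358, exact test), with Acta1 and Xirp2 unmarked.

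Energy metabolism, the cell cycle and ribosomal proteins were marked throughout. All 20 glycolysis genes, all 25 electron transport genes, all 28 cell cycle genes and all 24 ribosomal protein genes had a region at the TSS. Of the fatty acid oxidation genes, 25 of 26 did, the exception being Ucp3, a mitochondrial carrier, named after its value was seen. Adjusted p by Fisher's exact test was 1.2e-04 for glycolysis, 2.0e-05 for electron transport, 6.4e-06 for cell cycle, 2.2e-05 for ribosomal proteins and 1.4e-04 for fatty acid oxidation. The odds ratios were 27.5, 34.2, 38.3, 32.9 and 11.4. Imprinted and growth genes had 10 of 13 marked, with an odds ratio of 2.01 and an adjusted p of 0.296 in the exact test.

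Markers of vessel, valve and connective tissue cells were also marked. The endothelial list had 20 of 22 members marked, with Pecam1, an endothelial adhesion molecule, at a signal value of 6.06 (7.31 and 8.42 in the replicates). The fibroblast list had 17 of 19, with the collagen gene Col1a1 at 5.76 (5.17 and 5.06). Endocardial and valve genes had 11 of 12 and smooth muscle and pericyte genes 13 of 15. Unmarked members, named after their values were seen, were Tie1 and Vwf, Lum and Mfap5, Plvap, and Rgs5 and Lmod1. By Fisher's exact test the adjusted p was 0.00331 for endothelial (odds ratio 5.50), 0.0127 for fibroblast (4.69), and 0.0476 for both the endocardial (5.14) and the smooth muscle list (3.62). Epicardial genes had 8 of 14 marked (odds ratio 0.876, adjusted p 1, exact test), with Wt1, an epicardial transcription factor, at 5.46. Schwann and neural crest genes had 4 of 12 (odds ratio 0.354, adjusted p 0.0936, exact test) and passed as lower in the pooled list (0.0454). The endocardial call was lost with replicate 1 alone (adjusted p 0.409) and with replicate 2 alone (0.297), as was the smooth muscle call (0.0517 and 0.320). The fibroblast call was lost with replicate 1 alone (0.284), and the endothelial call with the most 5′ start of each gene only (0.0739). Of the 9 alternatives fixed beforehand, the endocardial call held in 2 and the smooth muscle call in 1.

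Macrophage and lymphoid markers were mostly unmarked. Of 17 macrophage genes, 1 was marked (odds ratio 0.0608, adjusted p 2.0e-05, Fisher's exact test). It was Spi1, a myeloid transcription factor, named after its value was seen. Of 17 lymphoid genes 3 were marked (odds ratio 0.161, adjusted p 0.00114, exact test), namely Foxp3, Lck and Cd4. Foxp3, a regulatory T cell factor, shared its peak with the TSS of the neighbouring Ppp1r3f. With replicate 1 alone, 7 of the 17 lymphoid genes were marked and the call was lost (adjusted p 0.195), as with the pooled list (9 of 17, 0.360). The erythroid list had 6 of 16 marked, without passing the exact test (odds ratio 0.414, adjusted p 0.0936); it passed as lower in the pooled list (0.0454) and with TSS windows of 500 bp (0.0499). Among these were the transferrin receptor Tfrc at a signal value of 12.2, the transcription factors Klf1 (7.14), Nfe2 (6.72) and Tal1 (5.58), and the red cell membrane gene Gypa (6.81). Hba-a1, an adult alpha globin gene, was unmarked, but only 26.8% of the sampled 32-base words around its TSS were unique in the genome, so reads from it may not have been placed. Hba-a2 (14.6%), Hbb-bt (53.7%) and Hbb-bs (65.9%), named after their values were seen, were likewise unmarked and under 90% unique. Slc4a1 (82.9%) and Gata1 (85.4%), also named after their values were seen, were unmarked but closer to that bound. Slc4a1 had a TSS peak in replicate 2's own list, with a signal value of 3.61. Of the 10 erythroid genes with unique TSS sequence, 6 were marked.

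Genes of other tissues were marked far less often. Regions lay at 1 of 20 pluripotency and germline genes (Dazl), 1 of 17 lung and gut genes (Foxj1), 2 of 23 hepatocyte genes (Foxa3 and Onecut1) and 5 of 24 neuronal genes (Celf4, Elavl4, Camk2a, Gabra1 and Slc17a7). They lay at 5 of 30 developmental factors that are classical Polycomb targets (Six1, Gsc, En2, Dlx5 and Lhx2) and at 11 of 37 Hox genes, with Hoxa4 the highest at 6.30. Adjusted p by Fisher's exact test was 6.4e-06, 2.0e-05, 6.4e-06, 4.2e-04, 1.2e-05 and 5.6e-04 for these 6 lists, with odds ratios of 0.0514, 0.0608, 0.0777, 0.189, 0.144 and 0.290. Skeletal muscle genes had 7 of 22 marked (odds ratio 0.324, adjusted p 0.0127, exact test), with Actn3, Mylpf, Ckm, Casq1 and Myog the highest. Myod1, the skeletal muscle determination factor, had no peak. The regions at Actn3, Mylpf and Foxa3 also touched the TSS of a neighbouring gene (Zdhhc24, Tbc1d10b and Sympk). Of the 37 marked blood and other-tissue genes taken by the naming rule, 33 had a TSS peak in both replicates' own lists. En2 and Lhx2, the latter at a signal value of 2.07, had none in replicate 1. Cd4 and Myog had none in replicate 2. Epidermal and epithelial genes had 9 of 21 marked, with Krt10 at 7.09, and did not pass (odds ratio 0.509, adjusted p 0.142, exact test). They passed as lower, with 6 of 21, at a −log10 p of at least 10 (0.0228), at a signal value of at least 4 (0.0208) and at the most 5′ start only (0.0224).

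**Figure D1:**
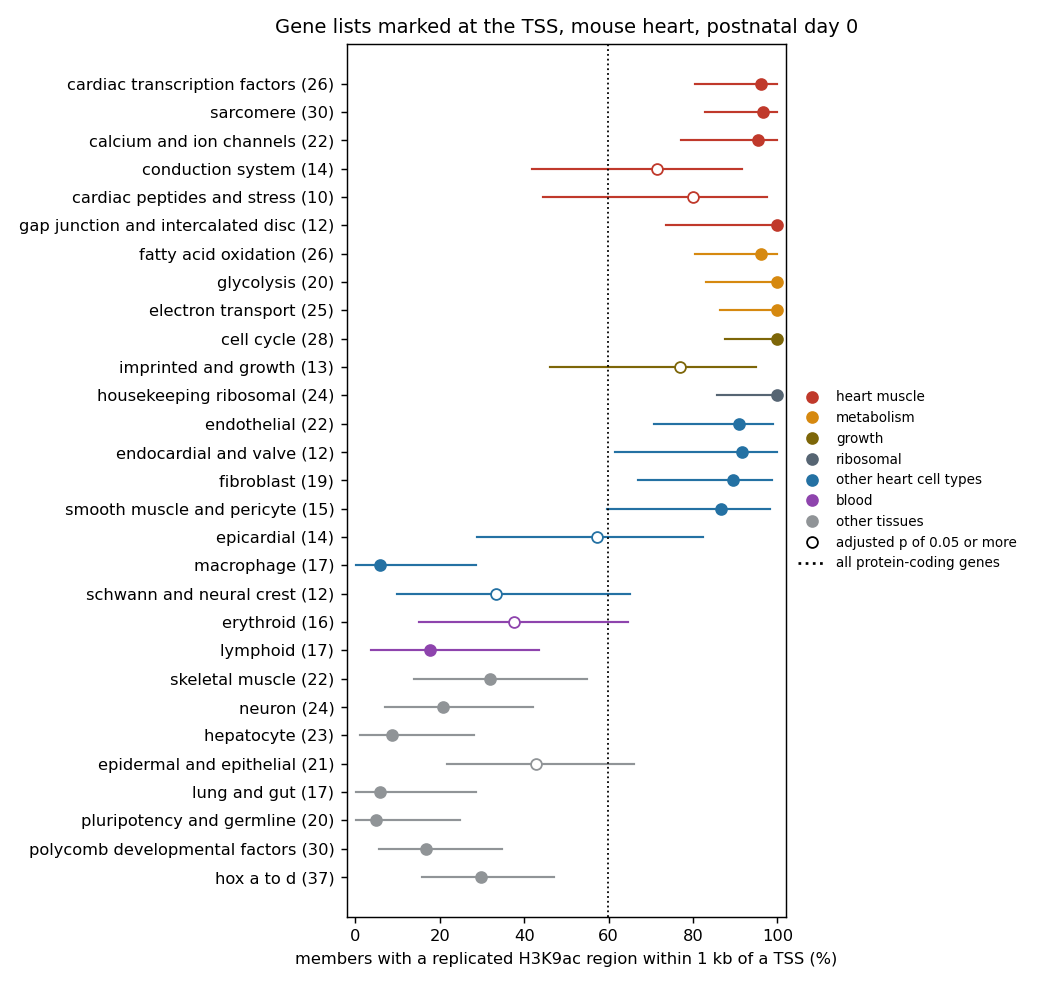
Share of members with a replicated H3K9ac region within 1 kb of a TSS (x axis, percent) for each of the 29 gene lists (y axis, number of members in brackets), with exact binomial 95% intervals as bars and the share of all protein-coding genes (59.9%) as the dotted line. Filled points passed Fisher's exact test; 13 lists lie above the line and 9 below it among these, such as sarcomere at 96.7% and macrophage at 5.88%.

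Marking differed by promoter class. With 1 TSS per gene, the most 5′ start, high-CpG TSSs were marked in 91.9% of 9808 genes (91.4 to 92.5), intermediate ones in 61.3% of 4058 (59.8 to 62.8) and low-CpG ones in 10.6% of 8072 (9.90 to 11.3), the last being the class of many tissue-specific genes. The odds ratio of high against low was 96.5, and the −log10 p of Fisher's exact test, of the upper tail, was 2965. Against genes with high or intermediate CpG content alone, 0 lists were higher at an adjusted p under 0.05. In that background 84.3% of other genes were marked, so lists marked in full did not pass either (sarcomere 11 of 11, adjusted p 0.387; cell cycle 27 of 27, 0.0648, exact tests). The lost calls therefore do not show that promoter class accounts for these lists. Among the lower lists 6 calls held, while the macrophage list had no member left to test. Of the lymphoid genes 1 of 3 left was marked and of the hepatocyte genes 2 of 5, which did not pass (adjusted p 0.160 and 0.109, exact tests). Among low-CpG TSSs alone, a background chosen after the data were seen, sarcomere genes were marked in 17 of 19 cases against 10.4% of other genes (adjusted p 8.3e-14, exact test). There the calcium and channel list had 6 of 8 (adjusted p 1.7e-04, exact test), the fibroblast list 9 of 11 (9.6e-07) and the endothelial list 7 of 10 (8.8e-05). Cardiac transcription factors, with 2 of 4, did not pass (adjusted p 0.130, exact test), but passed when marking at any of their TSSs counted (4 of 4, 0.00398), and at that TSS epicardial genes had 0 of 7. In that background 5 of 15 skeletal muscle genes were marked, above other genes (odds ratio 4.45, adjusted p 0.0428, exact test), the reverse of the result among all genes.

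The widest regions lay at cardiac transcription factor and myosin genes. Gata4 had the widest, 20850 bp on chromosome 14 (63236009 to 63256858) inside the gene, with 16916 and 15556 bp in replicates 1 and 2. Myh6 and Myh7, which lie next to each other, shared a region of 20532 bp (20455 and 16405 bp) that also lay within 1 kb of the predicted gene Gm17428. For Gata4 and Myh7 the wide region touched an annotated start within the gene, not the most 5′ one. Gata6 followed with 18707 bp (15262 and 13715 bp), Hand2 with 18056 bp (14159 and 11185 bp) and Nkx2-5 with 16724 bp (16709 and 10940 bp). The 10 widest also included Nfib, a transcription factor of organ maturation (14065 bp), Meis1, a regulator of cardiomyocyte cell cycle exit (14023 bp), and Irf2bp2 (13683 bp). The wide class began at 3488 bp. It held 19 of 25 marked cardiac transcription factors (median 5068 bp) and 22 of 29 marked sarcomere genes (median 5385 bp), against 9.88 and 9.86% of other marked genes. It also held 11 of 21 calcium and channel genes, 8 of 12 intercalated disc genes, 5 of 11 endocardial genes and 4 of 8 cardiac peptide and stress genes. Adjusted p by Fisher's exact test for these 6 lists was 1.3e-13, 2.0e-15, 1.3e-05, 2.5e-05, 0.0159 and 0.0243, and the odds ratios were 27.3, 27.4, 9.92, 17.1, 7.63 and 9.01.

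The other lists with at least 10 marked members had medians from 639 bp for Hox genes to 2741 bp for endothelial genes, and did not pass. Endothelial genes had 5 of 20 wide (adjusted p 0.139, exact test), imprinted and growth genes 4 of 10 (0.0530) and ribosomal protein genes 3 of 24 (1). Some of these lists passed under alternatives fixed beforehand. Ribosomal protein genes had 9 of 24 wide with joining across 3 kb (adjusted p 0.00231), and electron transport genes 8 of 25 without joining (0.0111). Endothelial genes passed at a −log10 p of at least 10 (6 of 18, 0.0255), and fatty acid oxidation (5 of 25, 0.0346) and imprinted genes (3 of 10, 0.0477, exact tests) in the widest 5%. The peptide call was lost with replicate 1 alone, with 3 of 8 wide (adjusted p 0.123, exact test). It was also lost when regions were joined across 3 kb (0.470). The endocardial call was lost without joining of neighbouring regions (adjusted p 0.238), with joining across 3 kb (0.596) and in the widest 5% (0.329).

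**Figure D2:**
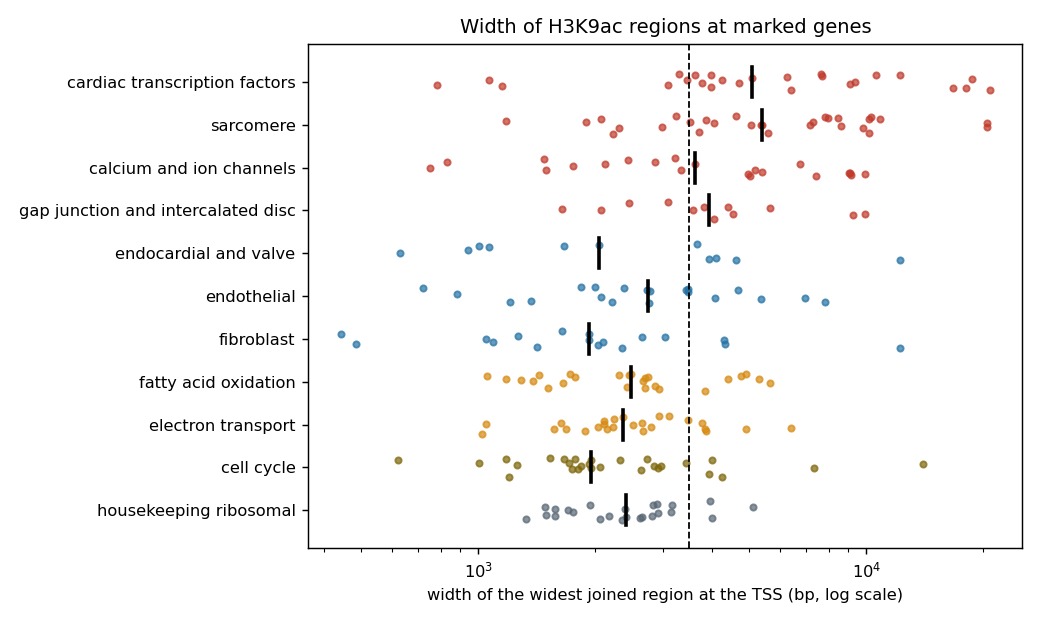
Width of the widest joined H3K9ac region at the TSS of each marked member of 11 gene lists (x axis, bp, log scale), 1 point per gene, with the list's median as a black bar and the lower bound of the widest 10% of marked genes (3488 bp) as the dashed line. The medians of cardiac transcription factors (5068 bp) and sarcomere genes (5385 bp) lie to the right of the line and that of ribosomal protein genes (2400 bp) to the left.

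Width and signal value ranked the gene lists differently, but overlapped at single genes. The 10 highest signal values at protein-coding genes belonged to broadly expressed genes, led by Ywhaz, a 14-3-3 adaptor protein, at 51.2. It was followed by Kcmf1 (46.3, with 42.7 and 34.1 in the replicates), Gtf2a1 (46.0), Mcl1 (45.6), Sfpq (45.3), Tnpo1 (45.2), Hipk3 (45.0), Nedd4 (45.0), Eif4a1 (44.5) and Fbxl3 (44.1). Their joined regions were 2184 to 5098 bp wide. Those of Ywhaz, Mcl1, Sfpq, Hipk3 and Nedd4 were in the wide class, and those of the rest were not. Among the 10 widest genes, Hand2, Irf2bp2, Nfib, Myh6, Nkx2-5, Gata6 and Gata4 were in the top 10% of marked genes by signal value. Meis1, Myh7 and Gm17428 were not. At Gata4 and Myh7 the signal value came from a TSS peak outside the wide region. When marked genes were ranked by signal value in place of width, an alternative added after the data were seen, the top 10% held 9 of 25 electron transport genes and 9 of 24 ribosomal protein genes (adjusted p 0.00654 for each, Fisher's exact test). The top 10% held 6 of 25 cardiac transcription factors and 5 of 29 sarcomere genes, which did not pass.

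**Figure D3:**
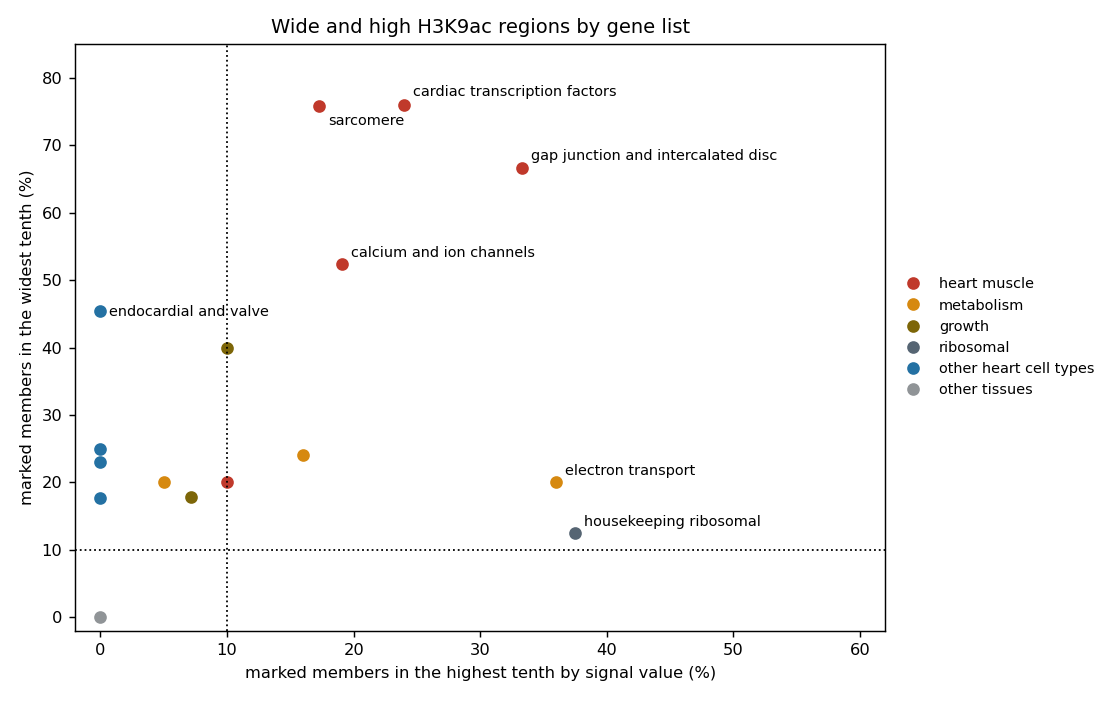
For the gene lists with at least 10 marked members, the share of marked members in the top 10% by width (y axis, percent) against the share in the top 10% by signal value (x axis, percent), 1 point per list, coloured by kind of list; dotted lines mark 10%. Of 25 cardiac transcription factors, 19 lie in the top 10% by width and 6 by signal value, and of 25 electron transport genes 5 and 9.

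The Myh6 and Myh7 locus shows how such a region is built. On chromosome 14, Myh6 (54941921 to 54966927) and Myh7 (54970684 to 54994626) are both read from the minus strand. The joined region ran from 54956392 to 54976923, from within Myh6 across its TSS into the 3′ part of Myh7. Myh7, the beta heavy chain, had its strongest TSS peak at 54988930 to 54995138, with a signal value of 11.7 (10.1 and 12.0), against 25.5 at Myh6.

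**Figure D4:**
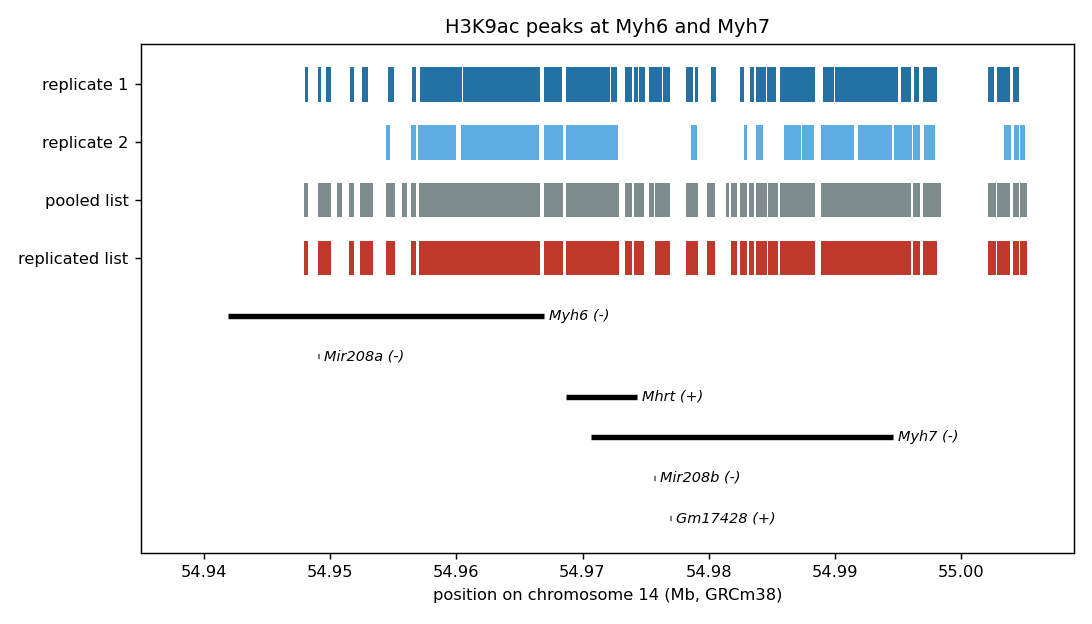
H3K9ac peaks (coloured blocks) of replicates 1 and 2 at a −log10 p of at least 5, of the pooled list and of the replicated list along chromosome 14 (x axis, Mb, GRCm38), above the annotated genes with their strand. In all 4 lists peaks lie on either side of the Myh6 TSS and at that of Myh7, and replicated peaks join into a region of 20532 bp around the Myh6 TSS.

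Away from TSSs, H3K9ac regions, counted singly, were more numerous near genes of some of the same heart muscle lists. Of 26630 regions on assembled chromosomes, 7346 were distal (27.6%, interval 27.0 to 28.1), with a median width of 534 bp against 1162 bp for the 17328 TSS regions. Cardiac transcription factors were the nearest gene of 93 distal regions, against 17.1 ± 8.65 (SD over random matched lists), with 12 at Gata4 and 11 at Gata6. Sarcomere genes were nearest to 55 against 9.35 ± 5.52, and calcium and channel genes to 53 against 13.1 ± 7.47, including 7 at Atp2a2. Adjusted p in the permutation test was 8.7e-04, 8.7e-04 and 0.0162. Of their members, 21 of 26, 18 of 30 and 13 of 22 had any distal region. Neighbouring regions were counted without joining, so a wide stretch of peaks can add several. Myh7, for example, was nearest to 7, and replicated peaks lay side by side within it. The counts may thus partly restate the width result, and joined regions were not tested. Over 5 kb from any TSS these lists had 69, 32 and 42 regions (adjusted p 0.0029, 0.0263 and 0.0263, permutation tests). The intercalated disc list had 29 against 6.59 ± 5.16 (adjusted p 0.0773, permutation test). None of the other lists passed. The closest were fatty acid oxidation genes with 27 against 8.29 ± 5.18 (0.0884), and epicardial genes had 0 against 6.01 ± 4.65 (0.222). With replicate 2 alone the calcium list no longer passed (adjusted p 0.0558), nor did it at a −log10 p of at least 10 (14 regions, 0.154), and with replicate 1 alone the intercalated disc list did (0.0309, permutation tests), as it did against random lists not matched on interval size (0.0151).

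The genes with most distal regions were Tns1, a focal adhesion protein, with 33, and Casz1, a transcription factor of cardiac development, Gse1, Sorbs1 and Zmiz1 with 22 each. The distal region with the highest signal value (32.3) lay on chromosome 15 (85669650 to 85673363), 63476 bp from Ppara, a regulator of fatty acid oxidation, within the noncoding gene Lncppara. The next lay near Chd7 (22.3, and again 21.0 at a separate region), Tpt1 (21.0) and Zfp869 (20.8). A RefSeq transcript start lay within 1 kb of 3 of these 5 regions: those near Chd7, with starts of Gm46842 and Gm8273, and the one near Zfp869, with starts of Zfp869 itself and Gm51532. These 3 are thus distal only in the annotation used.

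By placement, 61.6% of regions had their midpoint in a promoter (61.0 to 62.2), a class that makes up 6.05% of the genome. Introns held 23.7% (23.2 to 24.2), intergenic sequence 11.1% (10.7 to 11.4) and exons 3.69% (3.46 to 3.92). The promoter share was 37.7% in the pooled list. Annotated long noncoding RNA genes were marked in 22.1% of 10155 cases (21.3 to 22.9), and in 8.27% of the 7619 that lie over 2.5 kb from protein-coding TSSs (7.66 to 8.91).

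Sequence at the summits differed between distal and TSS regions. At distal summits the consensus of MEF2, a family of muscle transcription factors, occurred in 1.76% of regions against 0.762% of upstream flanks, and that of TEAD factors, which bind with the Hippo pathway coactivators, in 7.98% against 6.55%. ETS (1.02 against 0.381%) and SP/KLF (3.72 against 1.39%) sites were also more frequent. Adjusted p in the exact McNemar test was 1.8e-07, 0.00178, 3.6e-06 and 2.9e-19. The GATA consensus, bound by the cardiac factor Gata4 and its relatives, was less frequent at distal summits than in flanks (17.3 against 19.2%, adjusted p 0.00498, exact test). So were TBX5 (1.42 against 2.07%, 0.00498), NFY (632 against 883 of 7346 regions, 4.7e-11) and the OCT consensus (1.62 against 2.25%, 0.0104). At TSS summits ETS (2.33 against 0.427%), NRF1 (0.398 against 0.0231%) and SP/KLF (10.7 against 1.71%) were more frequent, with adjusted p of 1.9e-55, 7.8e-16 and 5.0e-285 in the exact test, and 10 of the 16 were less frequent, MEF2 among them (0.329 against 0.716%). Summit windows were richer in GC than flanks, 62.1 against 45.5% at TSSs and 51.9 against 46.5% at distal regions. At distal regions, shuffled MEF2 and TEAD sequences had median summit to flank ratios of 0.597 and 0.884, so base composition by itself shifts these ratios. The other consensus sequences were not set against shuffled ones. Whether their differences, higher or lower, reflect more than base composition was not tested. The MEF2 difference did not pass in regions with a −log10 p of at least 10 (adjusted p 0.350), and the TEAD difference did not pass with replicate 2 alone (0.0581) or in 200 bp windows (0.108), where ETS at distal and NRF1 at TSS summits did not pass either (0.0606 each). With replicate 1 alone the TBX5 difference did not pass (0.0790), nor did it at a −log10 p of at least 10 (0.0824) or in 200 bp windows (0.0606). Distal NRF1 (adjusted p 0.00576) and CTCF (0.0142, exact tests) passed with replicate 1 alone, and with flanks taken downstream (0.00883 and 0.00139). NRF1 also passed at a −log10 p of at least 10 (0.00735). In 200 bp windows distal CTCF turned to 8 summits against 20 flanks (adjusted p 0.0601, exact test), so its direction depends on the window. The consensus of NKX2-5, bound by the cardiac factor Nkx2-5, was lower at distal summits without passing (adjusted p 0.0555). It passed as lower with downstream flanks (4.1e-04) and at a −log10 p of at least 10 (0.0368), and distal SRF passed as lower in 200 bp windows (0.0237, exact tests). At TSS summits CTCF (0.0294) and HNF4 (0.0106) passed as lower and RFX (0.00122) as higher with downstream flanks alone.

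Genes on the X chromosome were marked less often than autosomal genes in these hearts pooled from both sexes. A region lay at 397 of 948 X-linked genes (41.9%) against 61.2% of 20807 autosomal genes. The odds ratio was 0.457, with a p of 1.1e-31 by Fisher's exact test. X-linked genes had a low-CpG TSS in 417 of 948 cases against 7491 of 20807, and mostly unique TSS sequence in 65.9% against 82.8%.

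The replicates gave similar counts for the heart lists. Sarcomere genes were marked in 29 of 30 cases in each replicate at a −log10 p of at least 5, and cardiac transcription factors in 23 of 26 in replicate 1 and 24 of 26 in replicate 2. No list passed the exact McNemar test, but none had enough members marked in 1 replicate only to pass after adjustment, so this does not show that the replicates were equal. At this minimum the largest gap was in the lymphoid list, with 5 members marked in replicate 1 only and none in replicate 2 only (p 0.0625, adjusted p 1, exact test), the smallest p that 5 such genes allow. Among the top 20000 peaks of each it was 2 and none, and the largest gap was in the fibroblast list, with none in replicate 1 only and 4 in replicate 2 only (p 0.125, exact test). Over all protein-coding genes, 696 were marked in replicate 1 only and 387 in replicate 2 only, a difference between these libraries (p 4.4e-21, exact McNemar test). The size of that difference depends on the peaks taken: 983 and 245 at a −log10 p of at least 10, and 596 and 444 among the top 20000 peaks of each. Genes marked in 1 replicate, with no peak of the other's list in their TSS windows, numbered 333 for replicate 1 and 178 for replicate 2. Those of replicate 1 were led by Mst1, Zscan10, Kifc1, Nubp1 and Fam241b, and those of replicate 2 by Tfpi2, Hpn, Gldc, Tnfrsf23 and Tspan17. A peak of the other replicate may lie just outside the window. The replicated peak at Mst1 ended at 108079783, before the most 5′ start at 108080436. Mst1, which encodes a liver-derived growth factor, had the highest signal value of these, 13.8 in replicate 1.

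Agreement of the replicates was high among the strongest peaks and lower when weaker peaks were included. Of all peaks, 45.0% of replicate 1 (44.6 to 45.5) were shared with replicate 2, and 50.4% of replicate 2 (49.9 to 50.8) with replicate 1. Among the top 10000 by −log10 p, 99.0 and 99.7% were shared. Over 22100 shared peaks, Spearman's rho was 0.773 for signal value and 0.735 for width, across peaks that are not independent. Of the pooled peaks, 44.1% were in the replicated list (43.7 to 44.5), from 1.01% in the lowest 10% by −log10 p to 100% in the highest. Of the replicated regions, 18439 were covered over at least 50% of their length by peaks of both replicates, 4744 by replicate 1 only, 2435 by replicate 2 only and 1016 by neither.

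**Figure D5:**
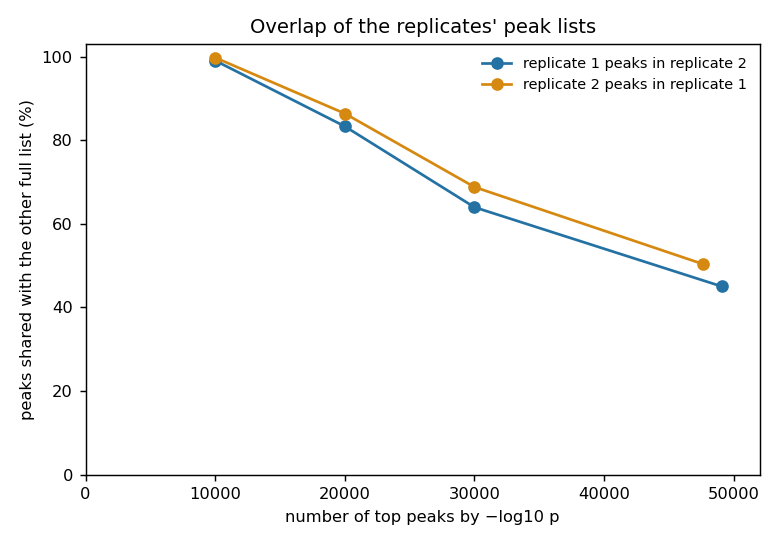
Share of each replicate's top peaks that overlap the other replicate's full list over at least 50% of their length (y axis, percent) against the number of top peaks by −log10 p (x axis), with 1 line per replicate and the full lists as the last points. The share falls from 99.0 and 99.7% of the top 10000 to 45.0 and 50.4% of all peaks.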

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

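The tests in this part were not chosen after the result was seen, since none was run. In data that entered no comparison, 4 replicated regions lay on unplaced or unlocalised contigs, sequence that belongs to the assembly but has no position on a chromosome. They had signal values of 9.87 on a contig assigned to chromosome 4, 6.70 and 11.6 on a contig assigned to the X chromosome, and 2.25 on an unassigned contig. No explanation was tested for these regions.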

How the results depend on the processing

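The backgrounds of low-CpG genes and of genes without neighbouring TSSs, and the ranking by signal value, were chosen after the data were seen. The CpG and X chromosome results passed with the same direction in all 5 alternatives fixed beforehand each, and the width calls of cardiac transcription factors, sarcomere, calcium and intercalated disc genes in all 6. The endocardial list call at the TSS held in 2 of 9, smooth muscle in 1, fibroblast in 5, lymphoid in 6 and endothelial in 7. Of 344 list results at the TSS under alternatives, 261 kept direction and side of the threshold. Replicate overlap (replicates 1 and 2) was 53.0 and 57.5% at 1 bp, 36.9 and 38.0% with reciprocal overlap, 57.2 and 70.8% at a −log10 p of at least 5, 77.4 and 93.4% at 10, and 73.5 and 78.5% among the top 20000 of each. The pooled share was 99.6% at 10. The promoter share was 79.9% at 10, 75.1% at a signal value of at least 4, 37.7% in the pooled list, 48.9% at 500 bp, 68.7% at 2 kb and 60.2 to 65.4% without a replicate. Marked genes were 55.6%, 56.6% and 64.4% under the first 3 of these, 60.6% at 2 kb, 56.3% at the most 5′ start and 57.3 to 58.8% without a replicate. The cause of these shifts was not tested. With high and intermediate CpG genes 0 lists were higher, in a background marked at 84.3% where short lists marked in full could not pass, and with 200 bp windows 2 motifs were higher at distal summits. With low-CpG genes 0 lists were lower, whether marked at that TSS or at any, which list size and the low base rate fixed: 0 of 17 macrophage and 0 of 18 hepatocyte genes at that TSS did not pass. Odds ratios turned for skeletal muscle (4.45 and 2.40) and, at any TSS, for Hox (4.58, 1 of 2 marked) and neuronal genes (1.96, 1 of 4, both with 0.5 added to each cell). At that TSS the odds ratio of 1.69 for Hox and for Polycomb targets comes from that 0.5 alone: 0 of 2 were marked in each, so the share stayed lower. 10 lists were higher under each definition: cardiac transcription factors (4 of 4) and imprinted genes (4 of 5) at any TSS only, intercalated disc and skeletal muscle genes at that TSS only, and 8 lists under both, with sarcomere at 18 of 19 against 17.8% of others at any TSS. By signal value 2 lists were higher, and the endocardial odds ratio turned to 0.391, with 0 of 11; the cause was not tested. Unknown depth limits all unmarked calls.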

Other observations

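The tests on Hox position and on chamber markers were chosen after the result was seen, as were the regions and genes named in this part. The bounds of the other tests were written before their results were seen, and the number of shuffled sequences was raised from 200 to 1000 after a first run.

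The region with the highest signal value of the replicated list lay at a noncoding gene. It spans 2605 bp on chromosome 7 (73555960 to 73558564) at the TSS of 1810026B05Rik, 14130 bp from the nearest protein-coding TSS. It ranked 1 by signal value in the pooled list and 4 in each replicate's own list (42.6 and 42.5). Other noncoding genes had wide joined regions. Among those away from protein-coding TSS windows, the widest was 11455 bp on chromosome 2 (180385576 to 180397030). It lay at B230312C02Rik and the microRNA gene Mir1a-1, which encodes a heart and skeletal muscle microRNA. The wider region of 20532 bp at Myh6, which also holds the noncoding genes Mhrt and Mir208b, is not part of this ranking. Malat1 had 9875 bp, Neat1 9507 bp, both nuclear RNAs, and Carmn, a regulator of smooth muscle and cardiac differentiation, 8372 bp.

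Hox genes split along their clusters. Of the paralog groups 1 to 4, which are expressed towards the head, 8 of 12 were marked, and of groups 5 to 13, 3 of 25 (p 0.00141, Fisher's exact test). Hoxd3 and Hoxd4, both among the marked genes of groups 1 to 4, were marked by the same peak. The test counts them as separate genes. A candidate explanation is that position along the clusters sets which Hox genes carry the mark in heart, which was found and tested on the same genes. Some atrial markers had weak regions. Over 10 atrial and 6 ventricular markers, the mean percentile of signal value was 53.8 against 79.3 (p 0.0212, exact permutation test), but Myl7, Nppa, Sln, Myl2 and Myh7 were classed as looked at before. Over the 7 atrial and 4 ventricular markers classed as not looked at before, the difference was −18.2 percentile points (p 0.158, exact permutation test). Ventricular Pln, counted among these 4, was however also a gene fixed by name, like Myl2 and Myh7. The second set is thus not free of genes already seen, and the difference without Pln was not tested. Atrial Myl4, with a signal value of 19.6, lay above ventricular Myl2 at 17.9, which had been looked at before, and below ventricular Myl3 at 24.0. The smaller mass of the atria as a candidate explanation thus stays open.

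Strong distal regions may partly be promoters missing from the annotation used. A RefSeq transcript start lay within 1 kb of 16.6% of the strongest 10% of distal regions and of 6.63% of the others (odds ratio 2.80, p 8.0e-18, Fisher's exact test). CpG-rich summits made up 15.9 and 2.30%. Most of the strongest distal regions have no such start.

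Wide regions at cardiac transcription factor and sarcomere genes were weighed against 3 technical explanations. If width followed peak height, lists matched on signal value would hold as many wide genes, but they held 7.30 ± 2.43 (SD) against 41 of 54 observed (p 2.0e-05, the smallest that the permutations can give). The signal value matched on was that of the strongest TSS peak, which at Gata4 and Myh7 lay outside the wide region. Lists matched on the number of annotated transcript starts held 5.49 ± 2.22 (p 2.0e-05). Among genes whose region touches no other protein-coding TSS, 35 of 46 were wide against 8.85% of others (odds ratio 31.8, p 1.2e-27, Fisher's exact test), which argues against joined neighbours. No biological explanation was tested, since the design has 1 group; a hypothesis is that genes of heart muscle identity carry extended acetylation, as found and tested on the same data.

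Fewer marked genes on the X chromosome were weighed against promoter CpG content and repeated sequence. Over CpG classes the Mantel-Haenszel odds ratio was 0.523 (0.441 to 0.621), and among genes with unique TSS sequence 0.749 (0.612 to 0.917). Both together may thus account for a part of the unadjusted 0.457, and as classed here they left a deficit. CpG content was held in 3 classes and, like uniqueness, taken at the most 5′ start, while marking counted any TSS. The test therefore cannot decide whether both account for the whole. Among unique genes with a high-CpG TSS, 91.6% of X-linked and 93.3% of autosomal genes were marked (p 0.335, Fisher's exact test), in the low-CpG class 44 of 200 and 1206 of 5058 (p 0.611), and in the intermediate class 126 of 210 and 2289 of 3264 (p 0.00251), so the deficit left rests mainly on 1 of the 3 classes. Signal values of marked X-linked genes with a high-CpG, unique TSS were lower by a log2 difference of −0.58 (−0.68 to −0.49), 8.86 over 197 genes against 13.3 over 8304 (p 2.0e-04, the smallest these permutations can give), while the medians of the 19 autosomes ran from 12.4 to 14.4 and the replicates gave −0.56 and −0.62. This is consistent with fewer active copies of the X chromosome in pooled males and females, and the DNA copy number itself, which the control correction may not remove, was not told apart from it.

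The MEF2 and TEAD consensus at distal summits were weighed against base composition, since summits are richer in GC than flanks. Shuffled sequences holding the letters CG had been left out and were not tested. None of 1000 shuffled MEF2 sequences without CG had a summit to flank ratio as high as 2.29 (0%, upper limit 0.368%, highest 1.61). For TEAD, with a ratio of 1.23, 1.5% did (0.842 to 2.46), after 2.5% of the 200 first drawn, under the bound of 5% in both runs. Within shuffles without CG, base composition alone is thus argued against for both. Each call was, however, lost under some alternative (MEF2 at a −log10 p of at least 10, TEAD with replicate 2 alone). No biological explanation was tested.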
